A study of Mus musculus with 4 samples.

How the data were processed

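RNA of a Treg and a T-effector sample of CD4 T cells was measured on 13 two-colour Agilent arrays of the whole mouse genome, with 45018 spots each, 1639 of them controls, for 41174 probes. Per the file headers, the spot values are scanner intensities, the mean signal and median local background of each dye, made with Agilent Feature Extraction 9.5.1.1. The processed intensities deposited beside them were background-subtracted, detrended and dye-normalized by that program, and the deposited log10 ratio is that of processed Cy5 over Cy3. The authors' value table holds 1 log2 value per probe and condition, whose scale and direction were set against the arrays. The dye of each sample was taken from the labels, and the direction of each array is Treg over T-effector.

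The analysis used limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50 and log ratios were normalized by loess within arrays. The default fit of the normexp parameters over all spots gave values far outside the background range on several arrays, and after this output had been seen the parameters were fitted without spots marked for their local background. The fit on all spots is an added alternative, and the parameters of 12 channels moved by over 10. Probes well above background in at least 3 of 26 channels were kept, 28969 in all, with at most 3 arrays missing. Probe names came from accessions (22951 probes), the files' own names (8455), symbols (6659) and synonyms (3109) in the reference table. Of each gene the probe with the highest mean signal was tested, which gave 19932 genes, 225 of them with a missing array.

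Treg and T-effector samples were compared by a fit of the log ratios with a gene-specific dye term over all 13 arrays (8 residual degrees of freedom). Conditions were compared within each sample type by a separate-channel fit after quantile normalization of mean signals, with an intraspot correlation of 0.45 (17 residual degrees of freedom). limma's moderated tests were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Slide as a block, and differences within slides holding both conditions, are given beside the results. Arrays are numbered in the order in which the labels list them. Arrays 1, 2 and 3 of TGFb and of TGFb with IL6 share slide and dye, and their deviations from the condition means, after removal of the dye term, correlated at 0.54 to 0.76 in the log ratio, 0.43 to 0.70 in Treg and 0.32 to 0.85 in T-effector samples. They were taken as 3 pairs, and the number was added as a replicate block after the data had been seen. The precision is limited by the number of arrays.

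The 20 gene lists were fixed before the data were examined: Treg core genes, genes lower in Treg, Th17, Th1 and cytotoxic, Th2, follicular helper, naive and memory, TGFb response, IL6 and STAT3 response, IL2 and STAT5 response, cell cycle, glycolysis and hypoxia, cholesterol synthesis, interferon response, chemokine receptors and adhesion, immediate early genes, and markers of B cells, myeloid and dendritic cells, CD8 and NK cells, and erythroid and stromal cells. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The genes named were also set by a rule fixed then: 12 anchor genes whatever their test, up to 4 members of each list with the largest change past the threshold, and the 5 highest and 5 lowest genes past the threshold whose arrays all go the same way, of which the text gives a selection. The Y-linked genes, their X-linked copies, Xist and 6 probes that move in step were chosen after their values were seen, except where the rule names them. A gene not well above background on any array of a group is given as a lower bound on its fold change.

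Alternatives were no dye term, Agilent's processed signals, no background subtraction, median centring (quantile normalization of all channels in the separate-channel fit), no filter, a stricter filter (well above background in every channel of at least 1 condition and sample type), every probe on its own, slide as a block, averaged arrays of a slide, each array left out and the authors' value table, with those added later named in the closing section. The removal of the spatial trend used medians of 19 by 5 blocks in 4 intensity classes. The fits were tested on simulated data with changes added to 1 condition. With log2 changes of 0.5, 1 and 2, 35.8%, 88.1% and 100% were recovered in a Treg against T-effector comparison (2.61% false), 5.97%, 74.6% and 97% in a ratio difference (5.6% false) and 26.9%, 82.1% and 97% in a comparison of conditions (5.52% false), and 0 genes were called in a condition left unchanged. The simulated errors were independent between arrays and between genes, with no effect of slide or pair. These shares therefore do not give the false rate where arrays of a slide or pair deviate together.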

Results

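Gene expression was measured in CD4 T cells from mouse lymph nodes, cultured on plates coated with anti-CD3 antibody at 1 ug/ml for 4 days. The cells were incubated for 3 days with IL2 at 100 units/ml, alone or with TGFb at 4 ng/ml, IL6 at 25 ng/ml or both. Anti-CD3 engages the T cell receptor and IL2 sustains the growth of activated T cells. TGFb is the cytokine that turns activated CD4 T cells into Foxp3-expressing regulatory cells in culture, and IL6 together with TGFb favours the Th17 lineage. The series title names the question: conversion to regulatory T cells (Treg) that depends on TGFb, and its inhibition by IL6. In each condition a Treg sample and a T-effector sample were labelled with opposite dyes and hybridised together on 1 two-colour array. There were 3 arrays for IL2, 3 for TGFb, 4 for TGFb with IL6 and 3 for IL6, which makes 13 arrays and 26 channels. Signals within these samples do not measure how many cells converted, so Foxp3 levels there do not answer the question of conversion or its inhibition. How the Treg and T-effector samples were separated is not in the labels, so a higher Foxp3 in Treg may reflect that step. The labels also do not say whether arrays of a condition came from separate cultures or animals. The p-values therefore measure only the spread between these arrays, which may be technical.

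The 13 arrays lay on 5 slides, called A to E here. Slides A and C held only arrays without TGFb, and slide B only arrays with it. IL2 and TGFb met only on slide D, with 1 array each, and TGFb with IL6 met IL6 alone only on slide E. Differences with TGFb therefore rest mostly on arrays of different slides. Treg RNA was in Cy5 on 2 of 3 arrays for IL2, 1 of 3 for TGFb, 2 of 4 for TGFb with IL6 and 1 of 3 for IL6. The share of probes well above background ran from 38.9% to 69.8% over the Treg channels and from 41.8% to 67% over the T-effector channels. On slide B the median Cy3 signal of the negative control spots was 118 to 123, against 3.59 to 25.4 on the other 4 slides. On slide E a spatial trend accounted for 31.5% to 51.2% of the variance of the log ratios of spots above the median signal. This share was 9.63% to 18.4% on slide D and 1.44% to 6.45% on slides A, B and C. After a filter on dim probes, 19932 genes were tested, each at 1 probe. Values below are log2 differences ± their standard error, with n as the number of arrays per condition given above.

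Foxp3, the transcription factor that defines regulatory T cells, was higher in Treg than in T-effector samples under all 4 conditions. Its log2 ratio was 2.39 ± 0.17 with IL2, 1.95 ± 0.17 with TGFb, 2.16 ± 0.14 with TGFb and IL6, and 2.12 ± 0.17 with IL6, in the same direction on 13 of 13 arrays (adjusted p = 2.22e-05, 5.99e-05, 1.54e-05 and 5.17e-05). Itgae, the integrin alpha chain CD103 of tissue-homing T cells, was higher by 2.46 ± 0.18, 3.22 ± 0.18, 2.49 ± 0.15 and 2.77 ± 0.18 in the same order. Ctla4, an inhibitory receptor of regulatory T cells, was higher by 1.49 ± 0.14, 0.62 ± 0.14, 0.48 ± 0.12 and 1.36 ± 0.14. Of the 28 measured members of the Treg core list, 19, 10, 12 and 14 were higher in Treg and 0 were lower (20, 16, 16 and 24 higher, and 1, 0, 1 and 0 lower, when adjusted over the list alone). The list shifted upward in each condition (camera adjusted p = 5.58e-17, 7.36e-11, 1.44e-12 and 8.25e-20), and the call held with an estimated correlation in all 4. With slide as a block its median log2 ratio was 1.01, 0.39, 0.37 and 0.89. Across conditions, 88 genes passed the threshold in all 4, of which 81 had the same direction in all 4, with 70 higher and 11 lower in Treg.

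**Figure D1:**
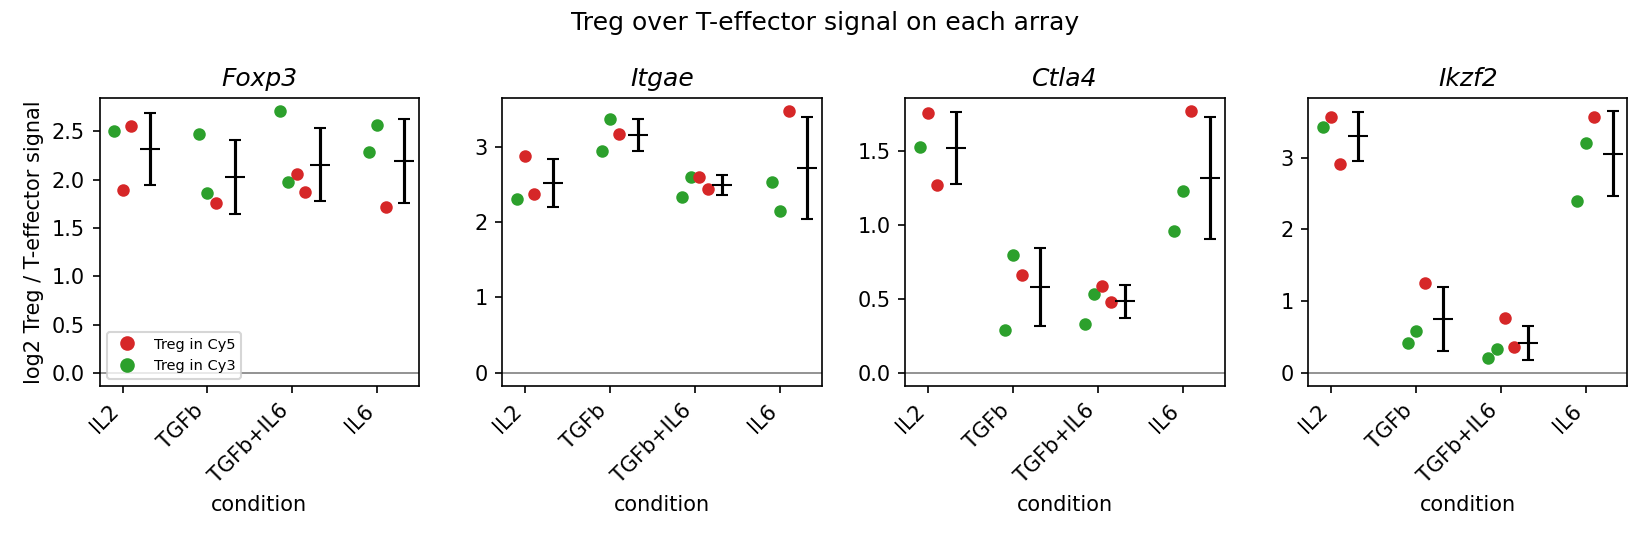
Log2 ratio of Treg over T-effector signal on each array (y axis) for Foxp3, Itgae, Ctla4 and Ikzf2, by condition (x axis). Points are arrays, coloured by the dye of the Treg sample, and black bars are condition means of the plotted points with their standard deviation over 3 or 4 arrays. Foxp3 and Itgae lie above 0 on all 13 arrays, and the fitted ratio of Ikzf2 was 3.23 ± 0.19 with IL2 and 3.12 ± 0.19 with IL6.

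With IL2 alone the Treg sample was also marked by Ikzf2 (Helios, 3.23 ± 0.19), a transcription factor of thymus-derived Treg, and by Itgb8 (3.01 ± 0.27), an integrin chain that activates latent TGFb. Cebpb (2.43 ± 0.28), Prdm1 (1.21 ± 0.18) and Socs3 (0.85 ± 0.20) belong to the list of genes induced by IL6 and STAT3. In that list 7 of 23 members were higher and 0 lower (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00047, and 0.168 with an estimated correlation). Lower in Treg were Prf1 (perforin, -1.15 ± 0.18), Gzmb (granzyme B, -0.79 ± 0.20) and Cd8a (-1.27 ± 0.36). Of the 13 CD8 T cell and NK cell markers, 3 were lower in Treg (4 adjusted over the list alone; camera adjusted p = 0.000182, and 0.161 with an estimated correlation). Of 14 B cell markers 0 were higher and 3 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.0606, 0.299 with an estimated correlation and 0.0176 with slide as a block, where the median was -0.15). Of the 20 genes of cholesterol synthesis, 6 were lower (8 adjusted over the list alone), among them Hmgcs1 (-0.74 ± 0.14) and Sqle (-0.73 ± 0.15), with camera adjusted p = 3.58e-05 and 0.427 with an estimated correlation. In total 2188 genes passed the threshold, 1479 higher and 709 lower in Treg. The count was 3380 with slide as a block, 5430 with Agilent's processed signals (2840 higher, 2590 lower), 5538 after removal of the spatial trend, 392 with the background model fitted on all spots, and 1055, 506 and 1426 without IL2 array 1, 2 or 3. Median centring in place of loess moved the median of all genes to -0.29 and the split to 1227 higher and 8479 lower. Directions here are therefore relative to the loess curve, and with median centring the ratio of Socs3 was -0.05.

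With TGFb the Treg sample had more Il2ra (1.09 ± 0.19), the high-affinity IL2 receptor chain, and more Ldlrad4 (1.78 ± 0.15) and Pmepa1 (0.78 ± 0.18), both inhibitors of TGFb signalling that TGFb induces. Of the 27 TGFb response genes 9 were higher and 1 lower in Treg (12 and 2 adjusted over the list alone; camera adjusted p = 4.65e-05, 0.00783 with an estimated correlation). Follicular helper genes were lower in Treg, 6 of 12, also 6 adjusted over the list alone (camera adjusted p = 3.13e-05, 0.00783 with an estimated correlation). They included Btla (-1.41 ± 0.13), Cd200 (-1.37 ± 0.11) and Il21 (-1.30 ± 0.31), the cytokine of follicular helper and Th17 cells. These lists' medians were 0.30 and -0.68 with slide as a block. Ighm, the immunoglobulin heavy chain of B cells, was higher in Treg (2.20 ± 0.11), as was Igh-VJ558 (2.79 ± 0.35), and 2 of 14 B cell markers were higher and 0 lower (2 and 1 adjusted over the list alone; camera upward with adjusted p = 0.604, 0.801 with an estimated correlation, median -0.01, mean 0.1). The threshold was passed by 1177 genes, 818 higher and 359 lower. The count was 1443 with slide as a block, 3317 with Agilent's signals (1709 higher, 1608 lower), 3340 after removal of the spatial trend (1831 higher, 1509 lower), 269 with the background model fitted on all spots, 482 with median centring (442 higher, 40 lower), 433 without slide B, and 459, 731 and 202 without TGFb array 1, 2 or 3.

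With TGFb and IL6 together the Treg sample had less Il17f (-0.59 ± 0.10), Il21 (-1.08 ± 0.27) and Il7r (-0.80 ± 0.10), the IL7 receptor of resting and memory T cells, and more Il1r1 (1.04 ± 0.11), the IL1 receptor of Th17 cells. Il17a was -0.39 ± 0.11, not past the threshold. Genes that Treg usually express less than other T cells were lower, 6 of 21 (10 adjusted over the list alone; camera adjusted p = 0.00439, 0.06 with an estimated correlation). Interferon-induced genes were also lower, 6 of 23 (10 adjusted over the list alone), with Rtp4 at -1.42 ± 0.36 and Ifit1 at -1.19 ± 0.28 (camera adjusted p = 0.000106, 0.0705 with an estimated correlation). With slide as a block the medians of these lists were -0.23 and -0.19. Ighm was higher in Treg by 2.21 ± 0.10. The threshold was passed by 1167 genes, 701 higher and 466 lower. The count was 1488 with slide as a block, 3601 with Agilent's signals (1623 higher, 1978 lower), 3616 after removal of the spatial trend (1803 higher, 1813 lower), 761 with the background model fitted on all spots, 268 with median centring, 619 with arrays of 1 slide averaged and 156 without slide B. It was 281, 450, 301 and 690 without TGFb and IL6 array 1, 2, 3 or 4, and 1987 without IL6 array 2.

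With IL6, as with IL2, the Treg sample had more Ikzf2 (3.12 ± 0.19) and Itgb8 (2.57 ± 0.27). Socs3, a feedback inhibitor of IL6 signalling, was higher by 1.39 ± 0.20, Cebpb by 1.87 ± 0.28 and Smad7, a feedback inhibitor of TGFb signalling, by 1.12 ± 0.11. The stefins Csta2 and Cstdc6, inhibitors of cysteine proteases, were higher by 3.25 ± 0.14 and 3.25 ± 0.09. Of 23 IL6 and STAT3 genes 6 were higher and 1 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.000628, 0.191 with an estimated correlation). Of 30 cell cycle genes 2 were lower, Ccnb1 (-0.72 ± 0.17) and Cdc6 (-0.43 ± 0.10), and 4 adjusted over the list alone (camera adjusted p = 0.00034, 0.405 with an estimated correlation). With slide as a block the medians of these lists were 0.37 and -0.36. The 13 CD8 T cell and NK cell markers shifted downward with 0 past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.0169, 0.369 with an estimated correlation; median -0.26 with slide as a block). Ighm was higher by 1.48 ± 0.11. Of 14 B cell markers 1 was higher and of 15 myeloid and dendritic cell markers 2 were, with 0 lower (1 and 2 higher, 0 and 0 lower adjusted over the list alone). Their camera adjusted p was 0.147 and 0.184, 0.386 and 0.437 with an estimated correlation, and 0.0244 and 0.0334 with slide as a block, where the medians were 0.14 and 0.16. The threshold was passed by 1160 genes, 748 higher and 412 lower. The count was 1270 with slide as a block, 3417 with Agilent's signals (1612 higher, 1805 lower), 3807 after removal of the spatial trend (2076 higher, 1731 lower), 743 without the offset of the background correction, 243 with arrays of 1 slide averaged and 443 without slide B. Median centring moved the median of all genes to -0.32 and the split to 498 higher and 8524 lower. The count was 169 without IL6 array 3 and 712 without TGFb and IL6 array 3.

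The genes that separated Treg from T-effector samples were more alike between conditions that differ in IL6 than between conditions that differ in TGFb. Across 19932 genes, which are not independent replicates, the log ratios of IL2 and IL6 correlated at r = 0.82 and those of TGFb and TGFb with IL6 at r = 0.74. The other pairs gave r = 0.04 for IL2 and TGFb, -0.08 for IL2 and TGFb with IL6, 0.17 for TGFb and IL6, and 0.08 for TGFb with IL6 and IL6 alone. Arrays that share slide and dye correlated at 0.82 for IL2 and IL6 and 0.66 to 0.84 for TGFb with and without IL6. For conditions that differ in TGFb they gave 0.06 to 0.66. Arrays of different slides correlated at 0.14 to 0.71, 0.12 to 0.53 and -0.36 to 0.3 in the same order. After removal of the spatial trend, arrays that share slide and dye gave 0.82, 0.66 to 0.75 and -0.1 to 0.45. Those of different slides then gave 0.26 to 0.68, 0.44 to 0.66 and -0.2 to 0.42. Shared slides may add to the likeness, and the counts expected of independent lists do not allow for it. Of the genes past the threshold with both IL2 and IL6, 702 of 702 had the same direction, where 127 shared genes would be expected of independent lists. With TGFb and with TGFb and IL6, 537 of 542 did, where 68.9 shared genes would be expected. The pairs that differ in TGFb also shared more genes than expected: 273 for IL2 and TGFb (129 expected), 255 for TGFb and IL6 (68.5), 231 for TGFb with IL6 and IL6 alone (67.9) and 319 for IL2 and TGFb with IL6 (128). Of these, 222, 234, 197 and 185 had the same direction. A set of 6 probes chosen after their values were seen moved in step across conditions: the median log2 ratio of the probes for Kcna7, Acsf2, Olfr741, Rab11fip5, Lrrc71 and Olfr430 lay between 1.22 and 1.73 on the IL2 arrays, between -2.53 and -1.87 on the 7 arrays with TGFb, and between -0.57 and 2.40 with IL6. Other probes of Rab11fip5 and Lrrc71 did not follow (0.18 and 0.05 with TGFb, against -2.18 and -2.08). They were well above background in only 5 Treg and 2 T-effector channels of 13 for Rab11fip5, and in 7 and 9 for Lrrc71. A probe near background can hide a change, so this comparison does not decide. The values are given for the probes, and whether they stand for the named transcripts stays open. Transcripts of the Y chromosome differed between the samples of 1 array: Ddx3y, Kdm5d and Uty were well above background in 11, 10 and 5 of 13 Treg channels and in 0 of 13 T-effector channels, and on IL6 arrays 1 and 3 in neither channel. Eif2s3y, also on the Y chromosome, was well above background in 13 Treg and 5 T-effector channels. Whether the 2 samples of an array came from the same animals is not known here. All Treg to T-effector ratios may therefore also hold differences between animals.

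The difference between Treg and T-effector samples itself changed with TGFb. When TGFb was compared with IL2, the Treg to T-effector ratio fell for Ikzf2 (-2.42 ± 0.27), Ctla4 (-0.86 ± 0.20) and Il2 (-0.91 ± 0.12), the T cell growth factor (Ctla4 differed by 0.02 with median centring). For Ctla4 the T-effector signal ran from 7.81 to 7.99 with IL2 and from 8.28 to 8.75 with TGFb. Its Treg signal ran from 9.08 to 9.65 and from 9.03 to 9.08. The ratio rose for Ldlrad4 (1.56 ± 0.21), the chemokine Xcl1 (1.56 ± 0.27) and Atp1b1 (2.38 ± 0.20), a sodium pump subunit. The ratio of Foxp3 differed by -0.44 ± 0.24, not past the threshold. Of the 28 Treg core genes 11 fell and 0 rose in the ratio (15 and 2 adjusted over the list alone; camera adjusted p = 0.000458, 0.0441 with an estimated correlation). Their median was -0.49, and -0.50 with slide as a block. In all, 1166 genes differed, 467 higher and 699 lower, and 1094 with slide as a block. The count was 3816 with Agilent's signals, 4109 after removal of the spatial trend, 73 with the background model fitted on all spots (44 higher, 29 lower), 226 without slide B, and 8405 with median centring (7453 higher, 952 lower), which moved the median of all genes to 0.42. Without single arrays it was 474 (IL2 1), 366 (IL2 2), 491 (TGFb 1), 607 (TGFb 2), 81 (TGFb 3), 547 (TGFb and IL6 3) and 1990 (IL6 2).

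Adding IL6 to TGFb changed the Treg to T-effector ratio of 58 genes, 20 higher and 38 lower. Cd24a, a surface glycoprotein of immature lymphocytes, fell (-2.25 ± 0.23), and Stat4 (0.88 ± 0.13), which carries IL12 signals, and Il6st (0.61 ± 0.11), the signalling chain of the IL6 receptor, rose. The ratios of Foxp3 (0.20 ± 0.22), Il17f (-0.52 ± 0.15) and Il17a (0.14 ± 0.17) did not pass the threshold. The follicular helper list shifted upward with 0 of 12 members past the threshold and 4 adjusted over the list alone (median 0.36, 0.31 with slide as a block; camera adjusted p = 1.64e-05, 0.0129 with an estimated correlation). The count was 108 with slide as a block, 14 in the paired fit with the array number as a replicate block (3 higher, 11 lower, with Stat4 at 0.89 and Il6st at 0.63 not past the threshold), 112 with Agilent's signals, 306 after removal of the spatial trend, 0 without slide B, 6 without the offset of the background correction (Stat4 and Il6st not past the threshold), 12 with the background model fitted on all spots (6 higher, 6 lower) and 9 with median centring (1 higher, 8 lower). Without single arrays it was 8, 21 and 4 (TGFb 1, 2 and 3), 10, 22, 7 and 9 (TGFb and IL6 1, 2, 3 and 4), 37 (IL2 2) and 103 (IL6 2). Adding IL6 to IL2 changed the ratio of 0 genes by limma. An unadjusted p under 0.05 was reached by 684 of 19932 genes, which is below a share of 0.05. Of the 12 anchor genes the largest ratio differences were those of Smad7 (0.73 ± 0.16) and Il2 (-0.64 ± 0.12). Without single arrays the count was 91 (IL6 2), 1 (IL6 1) and 1 (IL2 1), and without slide E it was 28. The B cell list shifted upward in that ratio with 0 of 14 members past the threshold and 3 adjusted over the list alone (median 0.25, 0.33 with slide as a block; camera adjusted p = 3.51e-08, 0.013 with an estimated correlation).

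Within Treg samples, TGFb compared with IL2 raised Nt5e, the ectoenzyme CD73 that makes adenosine, by 3.80 ± 0.38, or 13.9-fold (adjusted p = 3.92e-07). The water and glycerol channel Aqp3 rose by 4.26 ± 0.30, Itgae by 2.46 ± 0.25 and Xcl1 by 3.45 ± 0.21. Gata3, the Th2 lineage factor, changed by -2.33 ± 0.48, the opioid precursor Penk by -2.99 ± 0.21, the chromatin organiser Satb1 by -2.52 ± 0.18, Il2 by -1.85 ± 0.10 and the vasoactive peptide precursor Edn1 by -3.48 ± 0.32. Foxp3 differed by 0.23 ± 0.23 and did not pass the threshold. Of 27 TGFb response genes 11 rose and 3 fell (13 and 4 adjusted over the list alone), with Ldlrad4 at 2.57 ± 0.18, Tgfbr1 at 1.79 ± 0.18, Skil at 1.68 ± 0.12 and Smad7 at 1.37 ± 0.21 (camera adjusted p = 4.27e-06, 0.00138 with an estimated correlation). Follicular helper genes fell, 7 of 12 and 8 adjusted over the list alone, among them Tnfsf8 (-2.60 ± 0.34) and Bcl6 (-2.17 ± 0.52), their lineage factor (camera adjusted p = 2.38e-06, 0.000663 with an estimated correlation). Interferon-induced genes fell, 5 of 23 and 8 adjusted over the list alone, with Ifih1 at -2.04 ± 0.16 (camera adjusted p = 4.27e-06, 0.041 with an estimated correlation). The medians of the 3 lists were 0.39, -1.11 and -0.28 with slide as a block, and 0.35, -0.96 and -0.17 within slide D, which held both conditions. Igh-VJ558 rose by 4.72 ± 0.45 and Ighm by 1.16 ± 0.13, and the B cell markers Blnk and Cd79b changed by -2.34 ± 0.41 and -1.72 ± 0.27.

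In T-effector samples TGFb also raised Nt5e (3.87 ± 0.38) and Aqp3 (3.77 ± 0.30), and raised Ccl20 (4.16 ± 0.50), the chemokine ligand of the receptor on Th17 cells. Gata3 changed by -1.92 ± 0.48 and Tnfsf8 by -2.42 ± 0.34. Foxp3 was 0.67 ± 0.23 and Il17a -0.03 ± 0.18, neither past the threshold. Of 22 genes of glycolysis and hypoxia 6 fell and 0 rose (9 fell adjusted over the list alone), with the glucose transporter Slc2a3 at -1.82 ± 0.29, missing on IL2 array 2 (camera adjusted p = 3.04e-05, 0.398 with an estimated correlation). Of 14 B cell markers 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Blnk at -3.28 ± 0.41 and Cd79b at -2.70 ± 0.27 (camera adjusted p = 6.93e-05, 0.051 with an estimated correlation). The medians of these lists were -0.64 and -0.54 with slide as a block and -0.48 and -0.48 within slide D. TGFb changed 1553 genes in Treg (729 up, 824 down) and 872 in T-effector samples (383 up, 489 down), or 1085 and 661 with slide as a block. Within slide D, with 1 array of each condition, 99.9% and 100% of these genes had the sign of the fit, which includes those arrays. The counts were 2363 and 1458 with Agilent's signals and 2467 and 1518 after removal of the spatial trend. Without TGFb array 3 they were 1012 and 466, and the T-effector count was 497, 489 and 502 without IL2 array 1, IL2 array 3 or TGFb array 1.

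Adding IL6 to TGFb raised Th17 genes in both samples. Il17f, a signature Th17 cytokine, rose by 3.05 ± 0.12 in Treg and 3.57 ± 0.12 in T-effector samples (adjusted p = 2.94e-13 and 3.83e-14), Il21 by 4.54 ± 0.36 and 4.33 ± 0.36, and Il17a by 1.33 ± 0.17 and 1.20 ± 0.17. Ahr, a ligand-activated transcription factor that promotes Th17 cells, rose by 2.16 ± 0.18 and 2.92 ± 0.18. Foxp3 differed by 0.27 ± 0.21 and 0.07 ± 0.21 and did not pass the threshold in either. Il1r1 was not well above background on any TGFb array and was at least 8.59-fold higher in Treg and at least 4.13-fold higher in T-effector samples (adjusted p = 7.85e-13 and 7.5e-10). In the same way Serpinb5, a serpin, was at least 67-fold and at least 22.1-fold higher (adjusted p = 7.77e-12 and 1.89e-09). Of the 17 Th17 genes 7 rose and 0 fell in each sample (11 in Treg and 7 in T-effector adjusted over the list alone; camera adjusted p = 7.1e-16 and 5.28e-11, 7.82e-06 and 0.000107 with an estimated correlation). The median of the list was 0.76 in Treg and 0.60 in T-effector samples, or 0.72 and 0.61 with slide as a block. Within slides B, D and E it was 0.80, 0.55 and 0.76 in Treg and 0.86, 0.57 and 0.42 in T-effector samples.

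**Figure D2:**
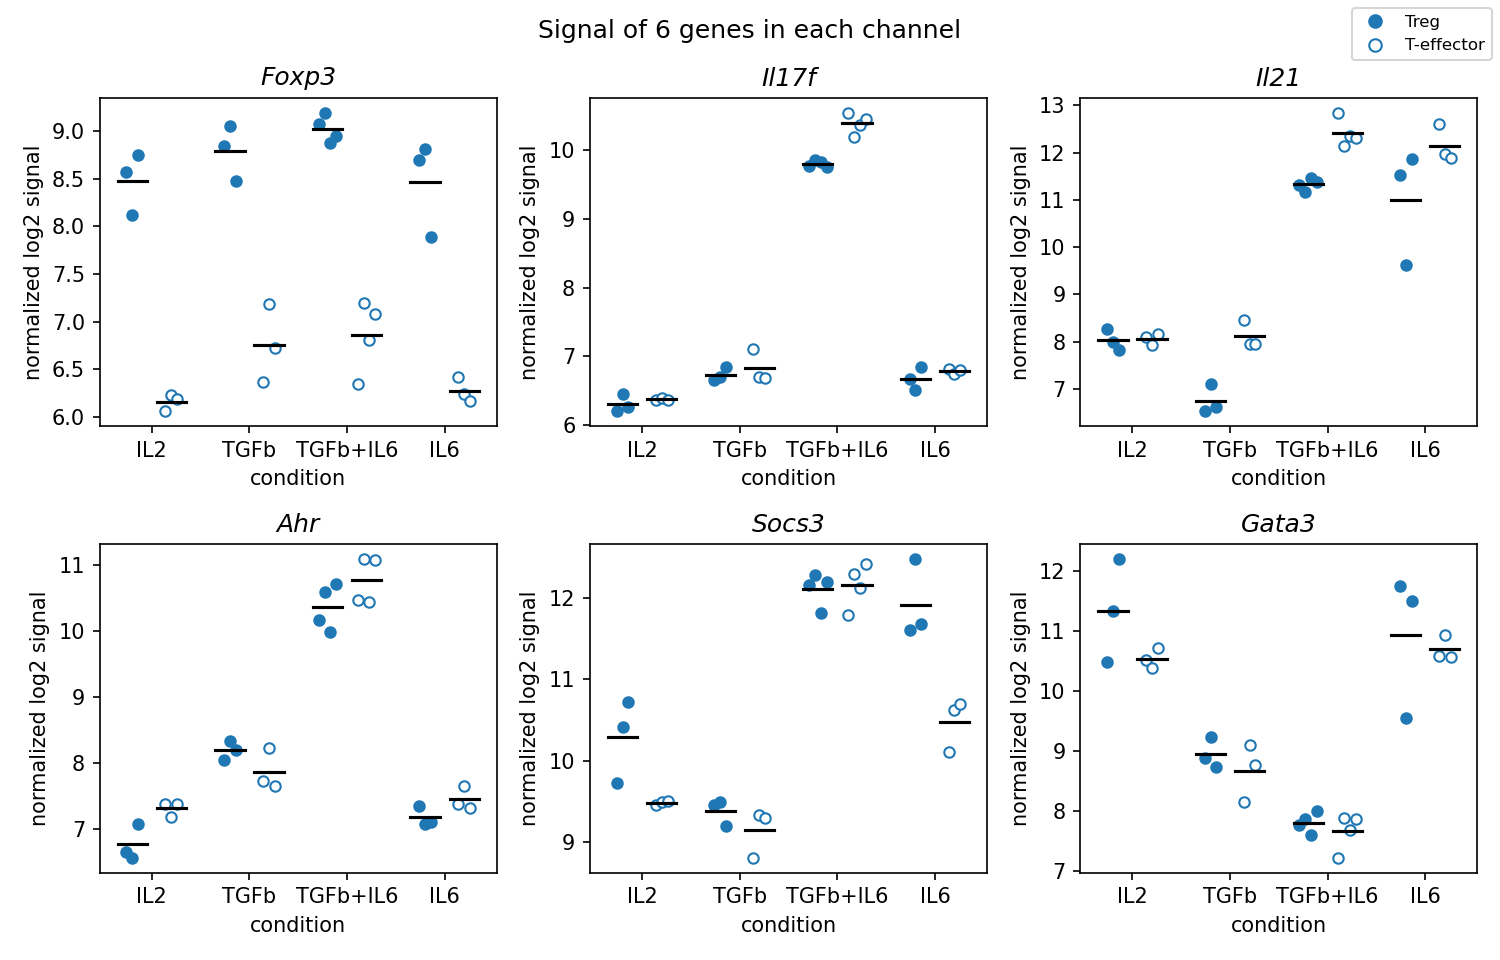
Normalized log2 signal of Foxp3, Il17f, Il21, Ahr, Socs3 and Gata3 in Treg (filled points) and T-effector channels (open points) by condition (x axis), 1 point per array, with bars at the means of 3 or 4 arrays. Il17f is highest in the condition with TGFb and IL6, where its mean was 9.80 in Treg and 10.39 in T-effector channels, and Foxp3 is higher in Treg channels in every condition.

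The IL6 and STAT3 list rose with IL6 on top of TGFb, 9 of 23 in Treg and 12 in T-effector samples with 0 falling (13 and 15 up, 1 and 1 down adjusted over the list alone), with Socs3 at 2.75 ± 0.24 and 2.98 ± 0.24 and Cebpd at 2.13 ± 0.24 and 1.73 ± 0.24. Its camera adjusted p was 1.44e-14 and 1.72e-15 and its call held with an estimated correlation. Genes of naive and memory T cells rose too, 8 of 16 and 10 of 16 with 1 falling in each (9 and 12 up, 1 and 1 down adjusted over the list alone; camera adjusted p = 5.87e-11 and 1.92e-12, held with an estimated correlation). Among them were S1pr1 (2.28 ± 0.41 and 2.57 ± 0.41), the receptor for exit from lymph nodes, and the T cell transcription factor Tcf7 (1.89 ± 0.26 and 1.87 ± 0.26). Within slides B, D and E the median of the STAT3 list was 0.81, 0.53 and 0.46 in Treg and 0.78, 0.71 and 0.59 in T-effector samples, and that of the naive and memory list 0.65, 0.50 and 0.60, and 1.06, 0.96 and 0.94. These medians were 0.65 and 0.83, and 0.63 and 1.01, with slide as a block. Il10, an anti-inflammatory cytokine, rose by 2.72 ± 0.29 and 2.50 ± 0.29. Among 25 chemokine receptor and adhesion genes 6 rose in Treg and 0 fell, and 10 rose and 1 fell in T-effector samples (8, 4, 10 and 1 adjusted over the list alone; camera adjusted p = 4e-05 and 1.7e-07, held with an estimated correlation). Their medians were 0.16 and 0.24 with slide as a block, and within slides B, D and E 0.16, 0.08 and 0.23, and 0.27, 0.14 and 0.24. The chemokine Ccl1 changed by -2.82 ± 0.45 and -2.13 ± 0.45, Penk by -2.16 ± 0.20 and -1.52 ± 0.20, and Ifng, the Th1 cytokine, by -1.62 ± 0.44 in T-effector samples (-1.60 with the array number as a replicate block, not past the threshold). The threshold was passed by 1119 genes in Treg (572 up, 547 down) and 1499 in T-effector samples (853 up, 646 down), or 1405 and 1807 with slide as a block. Of the genes past the threshold in both, 768 of 772 had the same direction, on the same arrays. The counts were 1858 and 2361 after removal of the spatial trend, 425 and 555 without slide B and 720 and 931 without slide E, and the T-effector count was 985 and 939 without TGFb array 1 or 3.

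Without TGFb, IL6 changed fewer genes than it did with TGFb, where 4 arrays stood against 3. Compared with IL2 alone, Il21 rose by 3.05 ± 0.38 in Treg and 4.02 ± 0.38 in T-effector samples, and Il17a by 0.79 ± 0.18 and 1.02 ± 0.18. Socs3 rose by 1.59 ± 0.26 in Treg and was 1.04 ± 0.26 in T-effector samples, not past the threshold there. Edn1 changed by -3.10 ± 0.32 and -2.48 ± 0.32, Penk by -2.18 ± 0.21 and -2.43 ± 0.21, and Il2 by -1.60 ± 0.10 and -0.96 ± 0.10. Il17f was 0.40 ± 0.13 and 0.39 ± 0.13, not past the threshold in either. Of 17 Th17 genes 3 rose and 1 fell in Treg and 4 rose in T-effector samples (6, 1 and 5 adjusted over the list alone; camera adjusted p = 8.12e-07 and 2.59e-10, held with an estimated correlation). The list's median was 0.32 and 0.21 with slide as a block and 0.24 and 0.41 within slide A. B cell markers fell in T-effector samples, 4 of 14 and 8 adjusted over the list alone, with Ighm at -1.65 ± 0.13 and Cd79b at -1.57 ± 0.27 (camera adjusted p = 2.7e-17, 4.93e-05 with an estimated correlation; median -0.48 with slide as a block and -0.48 within slide A). Markers of myeloid and dendritic cells fell as well, 3 of 15 and 5 adjusted over the list alone, with Cd74 at -0.79 ± 0.14 (camera adjusted p = 1.57e-06, 0.0105 with an estimated correlation; median -0.25 with slide as a block and -0.24 within slide A). The threshold was passed by 193 genes in Treg (82 up, 111 down) and 162 in T-effector samples (78 up, 84 down), or 102 and 73 with slide as a block. The counts were 410 and 257 after removal of the spatial trend, 88 and 86 with arrays of 1 slide averaged, and 330 (251 up, 79 down) and 90 (68 up, 22 down) without slide E. In Treg the count was 122 without the offset of the background correction, and 100, 561 and 94 without IL2 array 3, IL6 array 2 or IL6 array 3, and in T-effector samples 100, 98, 90 and 96 without IL2 array 1, 2 or 3 or IL6 array 3.

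In the presence of IL6, adding TGFb raised Il17f by 3.11 ± 0.12 in Treg and 3.61 ± 0.12 in T-effector samples, Ahr by 3.18 ± 0.18 and 3.33 ± 0.18, Nt5e by 3.42 ± 0.35 and 4.25 ± 0.35, and Aqp3 by 3.90 ± 0.28 and 5.28 ± 0.28. Gata3 changed by -3.16 ± 0.44 and -3.00 ± 0.44, and the peptide receptor Calcrl by -3.30 ± 0.22 and -3.50 ± 0.22. Ikzf2 fell in Treg (-3.00 ± 0.20). Il17a was 0.26 ± 0.17 and 0.14 ± 0.17 and Foxp3 0.59 ± 0.21 and 0.55 ± 0.21, none past the threshold. Genes of glycolysis and hypoxia fell, 13 of 22 in Treg with 2 rising, and 12 in T-effector samples with 1 rising (16 and 16 down adjusted over the list alone), with Slc2a3 at -1.23 ± 0.24 and -1.65 ± 0.24 and Tpi1 at -1.20 ± 0.18 and -1.47 ± 0.18. The list's camera adjusted p was 5.06e-07 and 2.33e-07, and the adjusted p with an estimated correlation was 0.181 and 0.126. Its median was -0.85 and -0.84 with slide as a block and -0.96 and -0.74 within slide E. Of 27 TGFb response genes 10 rose and 3 fell in Treg and 8 rose and 3 fell in T-effector samples (12, 3, 11 and 4 adjusted over the list alone; camera adjusted p = 0.000115 and 0.000264, held with an estimated correlation; medians 0.24 and 0.34 with slide as a block, 0.28 and 0.37 within slide E). The threshold was passed by 2016 genes in Treg (974 up, 1042 down) and 2235 in T-effector samples (1038 up, 1197 down), or 1714 and 2161 with slide as a block. The counts were 1175 and 1311 with arrays of 1 slide averaged, 1299 in Treg without slide B, 857 in T-effector samples without slide E, and 1270 and 1464 without IL6 array 3.

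The response to TGFb with IL6 present resembled that without it, and a test of the difference found genes of several lists, Th17 genes among them. Across all genes the 2 TGFb effects correlated at r = 0.64 in each sample. They share no array but are not independent. Arrays 1, 2 and 3 of TGFb and of TGFb with IL6 share slide and dye, as do IL2 array 1 and IL6 array 2. Deviations common to such arrays enter both effects, and the counts expected of independent lists do not allow for that. Of genes past the threshold in both, 866 of 876 in Treg and 555 of 567 in T-effector samples had the same direction, where 157 and 97.8 would be expected of independent lists. The effect of TGFb was more positive with IL6 for Il17f, by 2.66 ± 0.18 in Treg and 3.18 ± 0.18 in T-effector samples (adjusted p = 8.94e-09 and 8.19e-10), and for Ahr by 1.73 ± 0.27 and 2.80 ± 0.27. It was also more positive for Il10 (2.90 ± 0.43) in Treg and for Socs3 (1.94 ± 0.35) in T-effector samples. In Treg TGFb lowered Il2 less with IL6 (-0.57 ± 0.10) than without it (-1.85 ± 0.10), a difference of 1.28 ± 0.14. As given above, IL6 without TGFb also lowered Il2 in Treg, so its level was already lower where TGFb was added to IL6. For Foxp3 the difference was 0.35 ± 0.31 and -0.12 ± 0.31, not past the threshold. Of 17 Th17 genes 4 and 3 had a more positive TGFb effect with IL6 and 0 a more negative one (6 and 4 adjusted over the list alone; camera adjusted p = 4.51e-09 and 6.99e-05, 0.000293 and 0.0055 with an estimated correlation; medians 0.41 and 0.33 with slide as a block). For 16 naive and memory genes these counts were 3 and 4 with 0 more negative (5 and 10 adjusted over the list alone; camera adjusted p = 9.31e-07 and 1.26e-13, 0.0101 and 0.00126 with an estimated correlation; medians 0.32 and 0.88 with slide as a block). The IL6 and STAT3 list also shifted upward, with 2 and 2 of 23 more positive and 0 more negative (9 and 7 adjusted over the list alone; camera adjusted p = 9.31e-07 and 3.08e-06, 0.0101 and 0.0169 with an estimated correlation; medians 0.41 and 0.48 with slide as a block). In T-effector samples 14 B cell markers shifted upward with 0 past the threshold and 8 adjusted over the list alone (camera adjusted p = 3.5e-09, 0.00126 with an estimated correlation; median 0.48 with slide as a block), as did 23 interferon-induced genes with 2 past the threshold, also 2 adjusted over the list alone (camera adjusted p = 3.85e-06, 0.0286 with an estimated correlation; median 0.31 with slide as a block). The interaction passed the threshold for 186 genes in Treg (112 positive, 74 negative) and 199 in T-effector samples (142 positive, 57 negative), or 158 and 158 with slide as a block. The counts were 305 and 418 after removal of the spatial trend, 119 and 123 with arrays of 1 slide averaged, 102 and 84 without slide B, 123 in Treg without the offset of the background correction, and 448 and 304 without IL6 array 2.

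The authors' value table holds 1 column per condition. Each column matched the mean of 2 arrays of opposite dye on the log2 Treg over T-effector scale, with r = 0.962 for IL2 arrays 1 and 2, 0.96 for TGFb arrays 1 and 3, 0.963 for TGFb and IL6 arrays 1 and 3, and 0.967 for IL6 arrays 2 and 3. The column medians were -0.083, -0.054, -0.016 and -0.042. Scale and direction were found by this match, and how the authors centred the columns stays unknown. In the authors' deposited table Foxp3 was 3.669 with IL2, 3.4249 with TGFb, 3.4303 with TGFb and IL6 and 3.7257 with IL6. The fitted ratios given above were smaller. Without the offset of 50 in the background correction, a run chosen after the data had been seen, they were 3.54, 3.01, 2.91 and 3.08, and with Agilent's processed signals 4.31, 3.62, 3.26 and 3.57, so the size of the Foxp3 ratio depends on how the background is treated. Of the genes past the threshold in the fit, 100% in each condition had the same sign in that table, whose arrays the fit includes.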

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

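All tests of explanations in this part were chosen after the results had been seen. Differences between the effects in 2 groups were found by tests of the difference itself. The effect of TGFb differed with and without IL6 for 186 genes in Treg and 199 in T-effector samples. In Treg it differed for Il17f (2.66 ± 0.18), Il10 (2.90 ± 0.43), Ahr (1.73 ± 0.27) and Il2 (1.28 ± 0.14), and in T-effector samples for Il17f (3.18 ± 0.18), Ahr (2.80 ± 0.27) and Socs3 (1.94 ± 0.35). The Treg to T-effector ratio differed between TGFb and IL2 for 1166 genes, among them Ikzf2 (-2.42 ± 0.27), Il2 (-0.91 ± 0.12), Ctla4 (-0.86 ± 0.20), Atp1b1 (2.38 ± 0.20), Ldlrad4 (1.56 ± 0.21) and Xcl1 (1.56 ± 0.27). It differed between TGFb with IL6 and TGFb for 58 genes, among them Cd24a (-2.25 ± 0.23), Stat4 (0.88 ± 0.13) and Il6st (0.61 ± 0.11).

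Th17 genes rose in the Treg channel as in the T-effector channel when IL6 was added to TGFb. T-effector cells in the Treg sample would have to make up 76.3% of its RNA to give the median ratio of -0.39 of the 7 list genes called higher in both, and 161 of the 466 genes lower in Treg lie more than 2 standard errors below the lowest ratio that such a share allows. A difference between slides is argued against by the lowest of the list's medians within slides B, D and E, 0.42. A response of the Treg sample to IL6 may explain the pattern and stays a hypothesis.

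In 1 of 54 values tested over the 4 arrays with TGFb and IL6, 1 array lay apart from the others, where chance gives about 1 in 20. The ratio of Il21 was -1.52 on array 1, against -0.98 to -0.89 on the others. No biological explanation was tested for it.

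Other splits of the same arrays were counted for each comparison, the real split included. For TGFb with IL6 against IL6 in Treg, 1 of 35 splits gave as many genes as the real one (2016, highest other 347). The same held in T-effector samples (2235, highest other 287). It also held for the ratio difference between TGFb with IL6 and TGFb (58, highest other 0). This is the lowest share that 35 splits allow, with no adjustment for the number of comparisons. In each, chance can be excluded only if the arrays are taken as unpaired and slide is left aside. In the first, arrays with the same number correlated at 0.14 to 0.5 with the dye term left in. For TGFb with IL6 against TGFb, 2 of 35 splits gave as many genes in Treg (1119, highest other 2123) and in T-effector samples (1499, highest other 3800), so chance is not excluded by this count. In the last 4 of these results arrays with the same number correlated after removal of the dye term as well. Among the 8 splits that part all 3 pairs, too few for a share under 0.05, 1 gave as many genes in each, 2235 (highest other 54), 58 (highest other 0), 1119 (highest other 0) and 1499 (highest other 0). The ratio difference was 14 genes with the replicate block and 0 without slide B. The split with 2123 and 3800 genes keeps each pair together, sets the arrays of slide B against those of slides D and E, and points to a structure of the samples by slide. With slide as a block the counts were 1405 and 1807.

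The other comparisons have too few splits for a share under 0.05. With 4 splits, 1 gave as many genes for Treg against T-effector samples in IL2 (2188, highest other 1), TGFb (1177, highest other 0) and IL6 (1160, highest other 9), and 1 of 8 in TGFb with IL6 (1167, highest other 0). With 10 splits, 1 gave as many for TGFb against IL2 in Treg (1553, highest other 0) and T-effector samples (872, highest other 0), for the ratio difference between them (1166, highest other 0) and for IL6 against IL2 in T-effector samples (162, highest other 1). For IL6 against IL2 in Treg 3 of 10 did (193, highest other 963), where the highest split keeps the arrays of slide A together and those of slide E together, which points to a structure of the samples by slide, and the count was 102 with slide as a block. For the ratio difference between IL6 and IL2 all 10 did (0, highest other 558), where the highest split again keeps the arrays of slide A together and those of slide E together.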

How the results depend on the processing

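Removal of the spatial trend, a dye effect per slide, the replicate block, the background model fitted on all spots, normexp without its offset and leaving out slide B or slide E were chosen after the data had been seen, and the other alternatives before. Of 5298 values of genes named in the text under alternatives, 5042 counted as the same. Of the rest, 241 kept the direction and no longer passed, 13 newly passed and 2 reversed. A value counted as the same if it kept its direction and its side of the threshold. Values that passed in neither fit also counted so, whatever their direction. The 5042 include 48 values of the authors' table, which has no test, and 183 of the same probes in the fit of every probe. Without the offset of 50, Bcl6 in Treg with TGFb, Pmepa1 in the ratio with TGFb, Ctla4, Il17f and Il21 in that with TGFb and IL6, Ccnb1 and Cdc6 in that with IL6, and the ratio differences of Stat4 and Il6st between TGFb with IL6 and TGFb no longer passed. Both reversals came with median centring: Socs3 in Treg against T-effector samples with IL2 (-0.05) and the ratio difference of Ctla4 between TGFb and IL2 (0.02).

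Counts for Treg against T-effector samples in IL2, TGFb, TGFb with IL6 and IL6 were 5430, 3317, 3601 and 3417 with Agilent's processed signals, 5538, 3340, 3616 and 3807 without the spatial trend, 9706, 482, 268 and 9022 with median centring, and 1061, 433, 156 and 443 without slide B. The counts for IL2, TGFb, and TGFb with IL6 were 392, 269 and 761 with the background model fitted on all spots, and those for TGFb, TGFb with IL6, and IL6 were 2264, 3318 and 4467 with a dye effect per slide. With slide as a block the IL2 count was 3380. Averaging arrays of 1 slide gave 619 for TGFb with IL6 and 243 for IL6, the fit without the offset gave 743 for IL6, and leaving out slide E gave 3936 for IL2 and 1898 for IL6.

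Counts of ratio differences for TGFb against IL2, TGFb with IL6 against TGFb, and IL6 against IL2 were 3816, 112 and 4 with Agilent's signals, 4109, 306 and 11 without the spatial trend, 73, 12 and 2 with the background model on all spots, and 2504, 371 and 19 with a dye effect per slide. The first 2 were 8405 and 9 with median centring and 226 and 0 without slide B. With the array number as a replicate block the 3 counts were 453, 14 and 3. The second was 108 with slide as a block, 25 with no dye term, 30 with no background subtraction, 6 without the offset, 18 with arrays of 1 slide averaged and 18 without slide E. The third was 3 with no dye term, 1 without the offset and 28 without slide E.

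Counts within Treg and T-effector samples for TGFb against IL2 were 2363 and 1458 with Agilent's signals and 2467 and 1518 without the spatial trend. For TGFb with IL6 against TGFb they were 1858 and 2361 without the spatial trend, 425 and 555 without slide B, and 720 and 931 without slide E. For IL6 against IL2 they were 410 and 257 without the spatial trend, 102 and 73 with slide as a block, 122 in Treg without the offset, 88 and 86 with arrays averaged, and 330 and 90 without slide E. For TGFb with IL6 against IL6 they were 1175 and 1311 with arrays averaged, 1299 in Treg without slide B and 857 in T-effector samples without slide E. The correlation between IL2 and TGFb ratios was -0.23 with median centring and 0.17 with a dye effect per slide, that of TGFb and IL6 -0.18 with median centring, and that of IL2 and TGFb with IL6 0.11 with a dye effect per slide.

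With the replicate block the counts in Treg and T-effector samples were 1412 and 738 for TGFb against IL2, 1002 and 1278 for TGFb with IL6 against TGFb, 141 and 132 for IL6 against IL2, and 1830 and 1968 for TGFb with IL6 against IL6. Within the paired comparison it ended the calls of Ifng in T-effector samples and of Stat4 and Il6st in the ratio, and of no other gene named. In the T-effector samples with IL6 and with TGFb and IL6, deviations of arrays with the same number correlated at 0.17 to 0.71 after removal of the dye term, though only arrays 1 share slide and dye, and the block ended no call of a gene named. In the Treg samples of these 2 conditions they correlated at -0.15 to 0.35, with 0.35 for arrays 1, and at 0.14 to 0.5 with the dye term left in. Arrays with the same number share no slide between IL2 and TGFb (-0.61 to 0.51) or between IL2 and IL6 (-0.69 to -0.08). There the block left Il17a with IL6 in Treg (0.79) and the ratio difference of Ctla4 with TGFb (-0.84) not past the threshold.

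With 1 array left out, the Treg against T-effector counts ran from 506 to 3077 for IL2, 202 to 1608 for TGFb, 281 to 1987 for TGFb with IL6 and 169 to 1546 for IL6. The ratio differences ran from 81 to 1990, 4 to 103 and 0 to 91. Counts in Treg and T-effector samples ran from 1012 to 2005 and 466 to 1099 for TGFb against IL2, from 939 to 1759 in T-effector samples for TGFb with IL6 against TGFb, from 94 to 561 and 90 to 179 for IL6 against IL2, and from 1270 to 2215 and 1464 to 2321 for TGFb with IL6 against IL6. The correlation of IL2 and IL6 ratios ran from 0.61 to 0.82. Settings that leave out arrays also lower the residual degrees of freedom, and for the other changes the cause was not tested. Genes near background, from 38.9% to 69.8% of probes being well above it per Treg channel, limit what ratios can show.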

Other observations

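The tests of the samples' sex-linked transcripts, of slide E and of the 6 probes that move in step were chosen after the results had been seen. TGFb also moved Th1 and Th2 genes in both samples. Compared with IL2, Il18r1, the IL18 receptor of Th1 cells, rose by 2.44 ± 0.31 in Treg and 1.93 ± 0.31 in T-effector samples, and Ifng rose in Treg (1.84 ± 0.47). Ccl5, a chemokine of memory T cells, changed by -2.39 ± 0.20 and -2.14 ± 0.20, and Il4, the Th2 cytokine, by -2.37 ± 0.53 in Treg. Of 21 Th1 and cytotoxic genes 7 rose and 3 fell in Treg and 6 rose and 4 fell in T-effector samples (8, 4, 8 and 7 adjusted over the list alone; camera adjusted p = 0.159 and 0.924, 0.399 and 0.936 with an estimated correlation, upward in T-effector samples although the list's median there was -0.07 and its mean -0.03). Of 15 Th2 genes 4 rose and 4 fell, and 2 and 3 (4, 5, 4 and 4 adjusted over the list alone; camera adjusted p = 0.876 and 0.456, 0.94 and 0.718 with an estimated correlation).

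Single genes induced by IL2 through STAT5 rose with TGFb although IL2 was present in both conditions. Socs2, a feedback inhibitor of cytokine receptors, rose by 2.55 ± 0.33 in Treg and 2.23 ± 0.33 in T-effector samples, and Lta, lymphotoxin, by 2.27 ± 0.21 and 2.12 ± 0.21. Of 17 such genes 4 rose and 2 fell in Treg (5 and 3 adjusted over the list alone; camera adjusted p = 0.0332, 0.23 with an estimated correlation and 0.108 with slide as a block), and 4 rose and 1 fell in T-effector samples (6 and 4 adjusted over the list alone; camera adjusted p = 0.191, 0.433 and 0.32 in the same order). The list's median was 0.05 and 0.06 with slide as a block and -0.19 and 0.18 within slide D. Immediate early genes went both ways, with Egr1 at -1.14 ± 0.17 and Jun at 0.91 ± 0.10 in Treg, and of 20 genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.138, 0.399 with an estimated correlation). Of 7 erythroid and stromal markers 0 rose and 1 fell in Treg (0 and 1 adjusted over the list alone; camera adjusted p = 0.412, 0.462 with an estimated correlation).

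Y-linked transcripts were mostly above background in Treg channels alone: Ddx3y was well above background in 11 Treg and 0 T-effector channels, Kdm5d in 10 and 0, Uty in 5 and 0, and Eif2s3y in 13 and 5. Eif2s3y was missing on IL6 array 2, so the Y-linked value of an array is the median log2 ratio of the other 3. Their T-effector signals lie near background, so the size of these ratios is not that of a change in RNA. Gene-specific dye bias would change the sign of the ratio with the dye, and over the arrays of the 3 conditions other than IL6 with Treg in Cy5 the median was 0.50, with 0.14 as the lowest, while those with Treg in Cy3 ran from 0.46 to 1.29. Over all 13 arrays the lowest values were 0 with Treg in Cy5 and 0.06 with Treg in Cy3, both with IL6. Cross-hybridisation with the X-linked copies is argued against by their median ratio of -0.18. RNA of male animals alone in the Treg sample is argued against by Xist, the transcript of the inactive X chromosome, which was well above background in 13 of 13 Treg channels with a median log2 ratio of -0.10 (-1.25 to 0.55 over the arrays). Some RNA of male animals in the Treg sample, mixed with that of female animals, with RNA of female animals alone in the T-effector sample, would make the Y-linked ratio fall as that of Xist rises. Over 13 arrays r was -0.76 (permutation p = 0.00247, adjusted 0.015) and Spearman's rho -0.68 (permutation p = 0.0126, adjusted 0.0202), in 8 relations tested with 100000 resamples. The Xist ratio also went with the dye, from -1.25 to 0.19 with Treg in Cy3 and from -0.10 to 0.55 with Treg in Cy5. With each dye's mean removed r was -0.78 (permutation within dyes, p = 0.00375, adjusted 0.015), and with the paired arrays of TGFb and of TGFb with IL6 averaged as well it was -0.85 over 10 values (permutation p = 0.00825, adjusted 0.0165). With Eif2s3y included where measured these 4 values were -0.65, -0.73, -0.59 and -0.64 (permutation p = 0.0162, 0.00649, 0.047 and 0.0758, adjusted 0.0216, 0.0165, 0.0537 and 0.0758). Without the 2 arrays farthest from the median Y-linked ratio, and with no dye mean removed, r was -0.53, or -0.48 with Eif2s3y. As the relation with each dye's mean removed passes the threshold after adjustment with these 3 genes and not with Eif2s3y included, the explanation stays open. The share of such RNA was not estimated, and TGFb and IL6 array 4 had a Y-linked ratio of 0.50 with an Xist ratio of 0.03. The sources used here do not give the sex of the animals, and the IL6 arrays 1 and 3, where the 3 genes were in neither channel well above background, leave it open how far this applies to them. Eif2s3y was well above background in the Treg channel on these arrays too, as on all 13.

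On slide E arrays correlated by dye across conditions that differ in TGFb: the mean correlation was 0.64 for 2 pairs with the same dye and -0.24 for 2 pairs with opposite dyes, a gap of 0.88. The gap was 0.29 once the spatial trend was removed, as a trend on the slide would give, and 0.27 with Agilent's processed signals. It was 0.54 once the dye effect common to all slides was removed, which does not decide on that explanation. What the 6 probes that moved in step with TGFb have in common was not tested.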
